A study of Mus musculus with 6 samples.

How the data were processed

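The libraries were prepared from KP2 cells, a murine pancreatic cancer line from a KPC mouse (a genetically engineered mouse model of pancreatic cancer). Per the labels' protocols, Irak4 was knocked out by infection with lentiviral CRISPR vectors carrying guide RNAs against Irak4, RNA was harvested with Trizol, and mRNA was taken from total RNA with oligo-dT. The groups were wild type, Irak4 knockout (KO) and KO with rescue, with 2 libraries in each of the 3 groups, taken from the sample titles. The labels describe neither the rescue construct nor any vector in the wild-type cells. The labels also leave open whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

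Per the submitters' processing notes, the names listed are bcl2fastq, STAR 2.0.4b, Subread, featureCounts 1.45 and the genome build GRCm38, and the strand setting and annotation release are not given in the sources used here. Per the file headers, each deposited file gives a read count, a CPM and an RPKM for 41388 genes. The deposited CPM was the count scaled to the total of the counts in the file (largest difference 3.3e-11), and the deposited RPKM was that CPM per kilobase of the listed gene length (largest difference 8.0e-11). The counts were tested, and the authors' CPM and RPKM served only in these checks. No row lacked a gene identifier. Symbols were taken from the GENCODE M21 annotation for 40254 identifiers.

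Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12339 genes tested and 29049 not tested. Counts were scaled by TMM, and the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was fitted to all 6 libraries with 1 mean per group and 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p under 0.05 were called. Normalised CPM in the text is the CPM over the TMM-scaled library size, given as mean ± SD with n = 2 libraries per group. Fold changes are edgeR's fitted log2 fold changes, and their standard error (SE) is the fold change divided by the square root of the F statistic. Gene lists were tested on log2 CPM with a prior count of 2. A gene was counted as moved back where it was called in the KO against wild type and called in the opposite direction in the rescue against the KO, and as still changed where it was called in the same direction in the KO and in the rescue, both against wild type. The extent of return was the median over called genes of the rescue change divided by the KO change, both against wild type, so that 0 is the wild-type level and 1 the KO level.

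The groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Exceptions are the tests named as chosen later, and the Fisher's exact test below, which the plan did not list. Of 27 gene lists the 25 with at least 5 tested members were tested with camera in limma 3.58.1, with adjustment over the lists. A preset correlation of 0.01 was used, and then an estimated correlation. With the preset, camera takes its degrees of freedom from the number of genes. With the estimate it takes the 3 residual degrees of freedom, which leaves little power with 2 libraries per group. A list that did not pass with the estimate is therefore not shown to have failed through correlation. The share of a list's changed genes that moved back was compared with the other changed genes by a two-sided Fisher's exact test, adjusted over 23 lists. The rule named Irak4 and Has2, the 8 highest and 8 lowest fold changes for the KO against wild type and for the rescue against the KO, 5 and 5 for the rescue against wild type, for genes moved back and for genes still changed, and up to 3 called members of each list with the smallest adjusted p. The genes named for their fold change were called, had a mean of at least 5 CPM, an established symbol, and groups whose libraries did not overlap. Outside the rule, Isg20 and Ldha were named after their values were seen, as list members that moved against the others. Of 138 genes that the rule named, 34 have an exon overlapping a gene on the opposite strand, among them Irak4 (Twf1) and Has2 (Has2os), and without a stated strand setting reads from such pairs cannot be told apart. Counts of near-identical family members (Ifit3 and Ifit3b, the Oas genes, the H2 genes) depend on how shared reads were counted and are uncertain.

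Totals ranged from 7605328 to 11505983 counts per library. A gene with 0 counts was given a floor of 3 counts over the group, and ratios with 1 to 3 counts have a 95% interval; floors and intervals cover counting error only. On counts simulated for the 12339 genes with 200 genes changed, the test of KO against wild type recovered 64.2% of 1.5-fold, 82.1% of 2-fold and 93.9% of 4-fold changes, and 5.3% of its calls were unchanged genes. For rescue against KO these were 53.7%, 82.1%, 92.4% and 3.8%, and for rescue against wild type 73.1%, 80.6%, 97.0% and 9.2%. All simulated libraries had the same spread for a gene, so these shares do not cover the larger spread between the rescue libraries. The replicate pairs differed by more than counting noise (chi-square per degree of freedom 3.58 in wild type, 4.18 in the KO and 8.22 in the rescue), so no library was counted as a duplicate. Alternatives were DESeq2 1.42.0, RLE size factors, no filter and a stricter filter, limma-voom, fits of only the 2 groups compared, a replicate block, a test against a 1.5-fold change, and leaving out each library in turn. Chance overlap from shared libraries was simulated 20 times.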

Results

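The data were RNA-seq gene counts from KP2 mouse pancreatic cancer cells in 3 groups of 2 libraries: wild type, Irak4 knockout (KO) and KO with rescue. IRAK4 is the kinase that carries signals from Toll-like and interleukin-1 receptors towards NF-kB, and the design asked which transcripts change with its loss and which return with its rescue. The wild-type libraries held 8880121 and 10615611 counts, the KO libraries 11505983 and 8325604, and the rescue libraries 7836296 and 7605328. Gm42418, a non-coding gene on chromosome 17 with the most counts summed over all libraries, took 4.26% and 4.01% in wild type, 2.93% and 2.67% in the KO, and 3.88% and 3.86% in the rescue. Mitochondrial genes took 1.39% and 1.65%, 1.97% and 2.33%, and 1.86% and 1.3% in the same order. The biological coefficient of variation was 5.1% in wild type, 6.1% in the KO and 10.5% in the rescue, so the rescue libraries differed most from each other.

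Irak4 (ENSMUSG00000059883, GRCm38 chromosome 15, 94543643 to 94581815), the targeted gene, had 37.8 ± 0.18 CPM in wild type, 21.1 ± 0.98 in the KO and 352 ± 199 in the rescue (SD, n = 2). Its transcript was lower in both KO libraries than in both wild-type libraries, with a log2 fold change of -0.84 (SE 0.33) that did not pass the test (adjusted p = 0.057). In the rescue it rose over the KO by 4.06 (SE 0.32, adjusted p = 2.3e-04), with 3881 counts in the first rescue library and 1586 in the second. The counts do not separate reads of the endogenous gene from those of a rescue construct, and a guide-directed mutation need not lower the mRNA, so the level is a limited check of the labels. Has2 (ENSMUSG00000022367, chromosome 15, 56665627 to 56694539), a hyaluronan synthase, was 6.03-fold lower in the KO, at 29.4 ± 10.98 CPM against 180.4 ± 10.2 in wild type (log2 fold change -2.59, SE 0.22, adjusted p = 6.0e-06). It rose 4.53-fold in the rescue to 136 ± 38.5 CPM (adjusted p = 7.5e-04), where its log2 fold change against wild type was -0.41 (adjusted p = 0.161). Both genes lie on chromosome 15, whose median log2 fold change in the KO was -0.20 relative to that of all genes. The Irak4 difference passed the threshold in 5 of the other fits, those without a filter, with only the groups compared, with a replicate block, and without either rescue library.

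**Figure D1:**
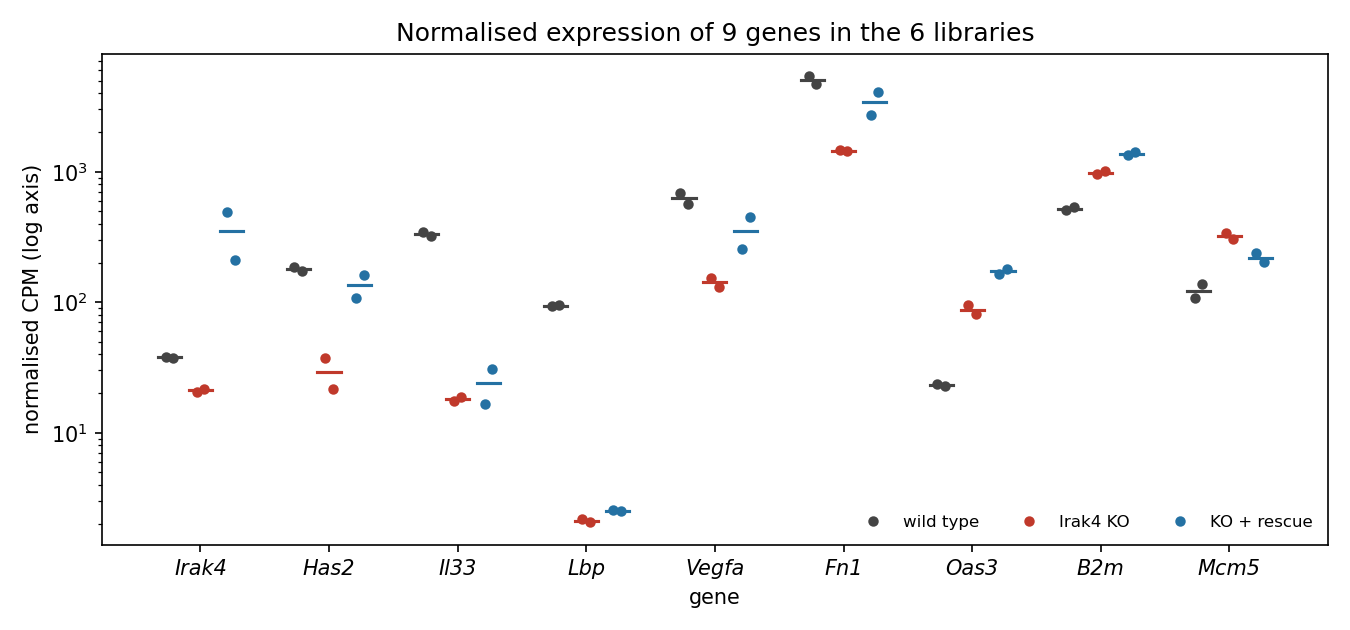
Normalised CPM on a log axis for 9 genes, with 1 point per library and a bar at the mean of the 2 libraries of each group. Lbp and Il33 stayed near the KO level in the rescue libraries, Has2 and Fn1 lay between the KO and wild type, and Oas3 and B2m were higher again in the rescue than in the KO.

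The KO differed from wild type over much of the transcriptome. In the KO 2867 genes were higher and 2905 lower among 12339 tested, and of these 457 were higher and 943 lower by at least 2-fold. Cxcl12, a chemokine, had 484 counts in wild type and 0 in the KO, at least 178.9-fold lower. Prom1 fell from 25.3 ± 0.78 to 0.18 ± 0.10 CPM and Celsr1, a planar polarity cadherin, from 56.7 ± 5.51 to 0.78 ± 0.04. Lbp, which encodes the lipopolysaccharide-binding protein, fell from 94.3 ± 1.83 to 2.12 ± 0.08 (adjusted p = 1.5e-09). Kcnn3, Mal, Atp2b4 and the integrin gene Itgb3 were also among the 8 genes with the lowest fold changes. Gpnmb, a glycoprotein of lysosomes and melanosomes, rose from 7.54 ± 1.77 to 247.5 ± 1.74 CPM (adjusted p = 5.2e-08), and the potassium channel subunit gene Kcnmb1 went from 1 count to 424, a ratio of 382 with a counting interval of 68.3 to 15136. Aadat, Col3a1, Slc6a15, Atoh8, Nova1 and Cmpk2 completed the 8 with the highest fold changes. A test against a 1.5-fold change called 479 genes higher and 927 lower. Without the first wild-type library 1688 genes were called higher.

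Inflammatory genes were lower in the KO. Of 29 tested NF-kB target genes, 26 fell and 1 rose (camera adjusted p = 2.9e-09, and adjusted p = 0.104 with an estimated correlation). Adjusted over the list alone the counts were also 26 and 1. Ptgs2, which makes prostaglandins, fell from 742 ± 3.76 to 122.7 ± 31.2 CPM, Cxcl1, a neutrophil chemokine, from 169 ± 19.0 to 41.6 ± 3.51, and Nfkbia, the NF-kB inhibitor, from 140.1 ± 8.48 to 40.8 ± 0.81. Of 29 secreted cytokines and chemokines 20 fell and 3 rose, the same numbers as adjusted over the list alone (camera adjusted p = 1.4e-05, and adjusted p = 0.122 with an estimated correlation). Il33 fell from 333 ± 17.8 to 18.2 ± 1.02 CPM and Csf3 from 33.1 ± 0.23 to 4.04 ± 0.20. The cytokine list shares members with the NF-kB targets, Cxcl1, Ccl2 and Lif among them, so these results are not independent. Other lists share genes too, such as Myc, and the lists called are not separate results throughout. Among 24 tested components of the Toll-like and interleukin-1 receptor pathway 4 rose and 4 fell, or 4 and 3 adjusted over the list alone. The list did not pass the test (adjusted p = 0.798), with 2 fallen members without any 1 of the wild-type and KO libraries and 7 risen without the second rescue library. Myd88, the adaptor that binds IRAK4, rose from 11.1 ± 0.44 to 23.2 ± 0.22 CPM, and the double-stranded RNA receptor gene Tlr3 from 15.1 ± 0.42 to 39.2 ± 4.86. Immune checkpoint genes fell in 8 of 12 tested and rose in 2, also when adjusted over the list alone, with Nectin2 and Cd47 among those that fell (adjusted p = 0.008, and adjusted p = 0.268 with an estimated correlation).

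Interferon-stimulated genes and antigen presentation genes were higher in the KO. Of 37 tested interferon-stimulated genes 33 rose and 1, Isg20, fell, also when adjusted over the list alone. The median log2 fold change was 1.47 (camera adjusted p = 1.2e-12, and adjusted p = 0.268 with an estimated correlation). Oas3, a sensor of double-stranded RNA, rose from 23.2 ± 0.39 to 87.9 ± 9.92 CPM, Oasl2 from 23.7 ± 0.29 to 81.0 ± 6.89, and the membrane tether gene Bst2 from 70.8 ± 1.84 to 204.0 ± 3.51. Of 20 MHC class I presentation genes 16 rose and 0 fell, and 17 rose when adjusted over the list alone (camera adjusted p = 1.4e-08, and adjusted p = 0.104 with an estimated correlation). Nlrc5, the activator of MHC class I genes, rose from 26.5 ± 0.92 to 94.5 ± 7.58 CPM, and the immunoproteasome gene Psmb8 from 3.67 ± 0.48 to 17.2 ± 1.12. Abundant genes of immune cells stayed low, with a median over 7 of them of 0.13 CPM in the library where it was highest.

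Growth-related lists rose while hypoxia, matrix and MAPK lists fell. Of 36 DNA replication genes 33 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 2.9e-11, and adjusted p = 0.309 with an estimated correlation). Mcm5, a helicase subunit gene, rose from 122.1 ± 21.4 to 324 ± 25.2 CPM. Of 30 MYC and ribosome biogenesis genes 26 rose, also when adjusted over the list alone (camera adjusted p = 8.7e-08, and adjusted p = 0.353 with an estimated correlation). Myc itself fell from 232 ± 2.07 to 139.9 ± 17.0 CPM, and Ldha was the other member that fell. Mitosis genes rose in 17 of 30, or 18 adjusted over the list alone (adjusted p = 6.5e-05, and adjusted p = 0.405 with an estimated correlation). Cdc20 was among them, and 11 rose without the first wild-type library. Of 34 hypoxia and glycolysis genes 31 fell, or 33 adjusted over the list alone, and 0 rose (adjusted p = 1.1e-10, and adjusted p = 0.337 with an estimated correlation). Vegfa was at 142.0 ± 16.1 CPM against 627 ± 86.2 in wild type, and Car9, a carbonic anhydrase, at 4.62 ± 1.09 against 72.0 ± 8.90. RAS-MAPK output genes fell in 24 of 28, or 27 adjusted over the list alone (adjusted p = 2.9e-09, and adjusted p = 0.294 with an estimated correlation). Ier3, Dusp1 and Hbegf had the smallest adjusted p among them. Collagens and matrix proteins fell in 22 of 34 and rose in 2, also when adjusted over the list alone (adjusted p = 6.3e-05, and adjusted p = 0.469 with an estimated correlation). Fn1, which encodes fibronectin, went from 5059 ± 463 to 1452 ± 7.74 CPM, and the laminin gene Lamb3 from 14.8 ± 0.24 to 1.40 ± 0.03. Hyaluronan genes fell in 8 of 14 and rose in 2, also when adjusted over the list alone, among them Has2, Hyal1 and Ugdh (adjusted p = 0.031, and adjusted p = 0.294 with an estimated correlation). That list did not pass without the first KO library (adjusted p = 0.089) or with a stricter filter (adjusted p = 0.053). In all, 5 lists were called higher and 14 lower of 25 tested, and 0 remained called with camera's estimated correlation, where 4 had an unadjusted p under 0.05. The estimated setting has only the 3 residual degrees of freedom, where the preset draws on the number of genes. A higher correlation was not the reason for every loss. The estimate was -0.020 for NF-kB targets, 0.001 for cytokines and chemokines and 0.004 for MHC class I genes, below the preset 0.01. The fry test, which asks whether the members of a list move one way on balance and sets them against no other genes, called 22.

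**Figure D2:**
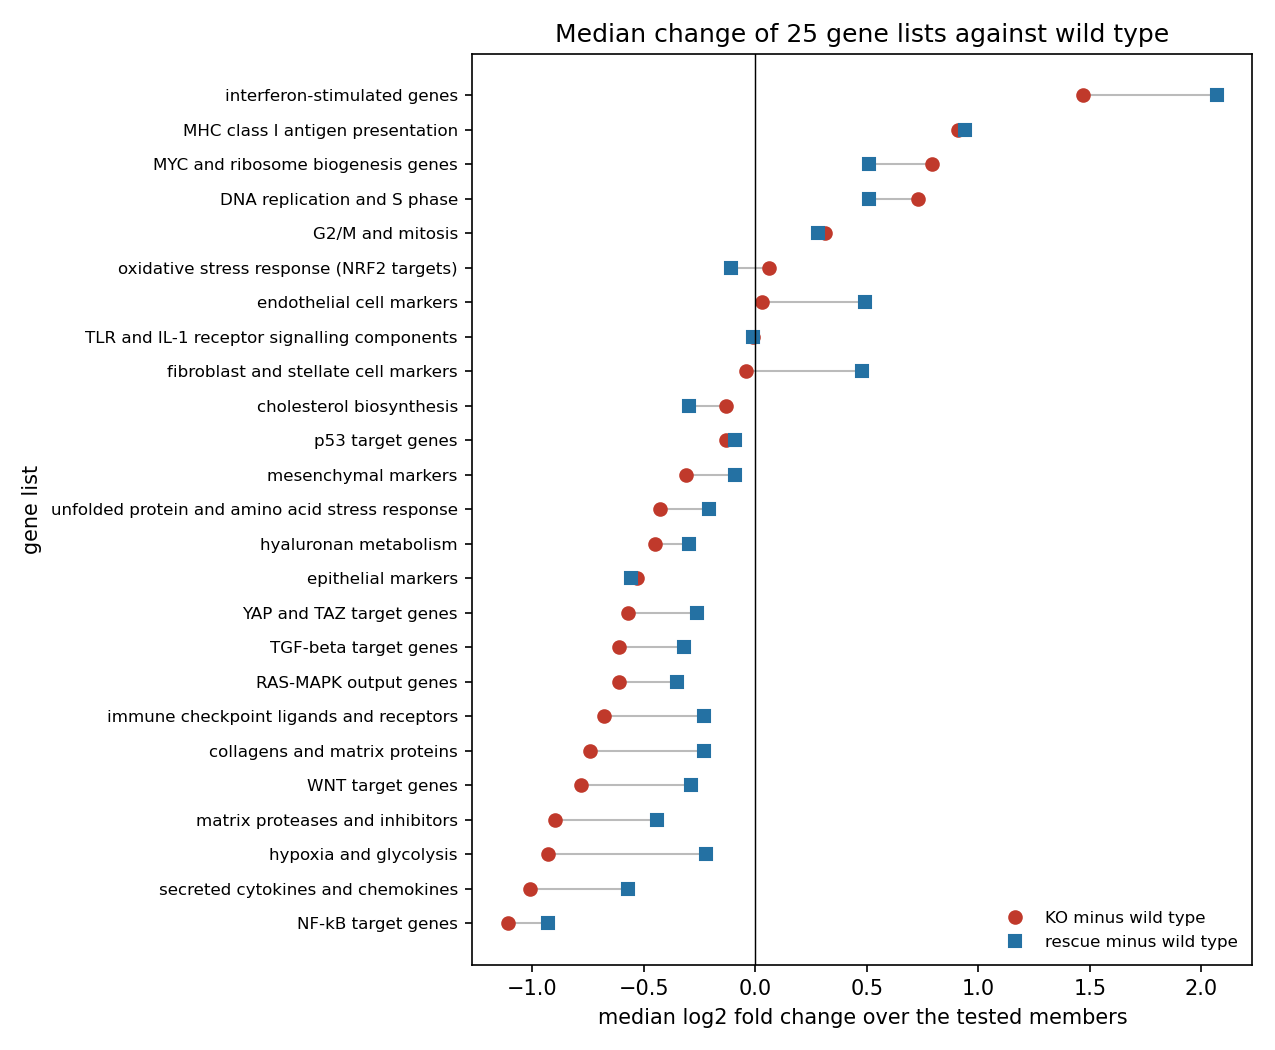
Median log2 fold change over the tested members of 25 gene lists, with circles for KO minus wild type and squares for rescue minus wild type, joined by a line for each list. Interferon-stimulated genes moved from 1.47 in the KO to 2.07 in the rescue, while hypoxia and glycolysis genes moved from -0.93 to -0.22.

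The rescue was compared with the KO to find the transcripts that differed between them. Irak4 stood at 492 and 211 CPM in the first and the second rescue library, above its wild-type level, and the construct is not described. The differences therefore cannot be put down to a return of Irak4 alone. In the rescue 1030 genes were higher and 726 lower than in the KO, with 206 higher and 81 lower by at least 2-fold. Hypoxia and glycolysis genes rose in 28 of 34, or 32 adjusted over the list alone, and fell in 0 (camera adjusted p = 2.7e-12, and adjusted p = 0.542 with an estimated correlation). The mitophagy gene Bnip3 rose from 73.0 ± 8.64 to 174 ± 44.2 CPM and the glucose transporter gene Slc2a1 from 329.8 ± 44.3 to 595 ± 122. Matrix genes rose in 19 of 34, or 21 adjusted over the list alone, and fell in 1 (adjusted p = 6.0e-07, and adjusted p = 0.542 with an estimated correlation). Fn1 rose to 3410 ± 953 CPM, and Thbs1 was at 283 ± 94.6 against 80.4 ± 18.0. RAS-MAPK output genes rose in 15 of 28, or 19 adjusted over the list alone (adjusted p = 1.1e-07, and adjusted p = 0.542 with an estimated correlation). Ier3 and Hbegf were among them. Interferon-stimulated genes rose in 22 of 37, or 28 adjusted over the list alone, and fell in 0 (adjusted p = 6.4e-11, and adjusted p = 0.542 with an estimated correlation). Oas3 rose to 172.5 ± 9.55 CPM and Ifi44 from 41.5 ± 3.45 to 81.3 ± 2.81. MHC class I genes rose in 8 of 20 and fell in 0, or 10 and 2 adjusted over the list alone (adjusted p = 0.005, and adjusted p = 0.542 with an estimated correlation). B2m was among those that rose. NF-kB targets rose in 6 and fell in 6 of 29, or 7 and 7 adjusted over the list alone (adjusted p = 0.995), with Tnfaip3 and Lif higher and Ccl2 lower, and 0 rose and 0 fell without the second KO library. DNA replication genes fell in 8 of 36, or 16 adjusted over the list alone (adjusted p = 4.0e-06, and adjusted p = 0.542 with an estimated correlation). Atoh8, Lgals4 and Wnk4 were among the genes with the lowest fold changes. In all, 9 lists were called higher and 4 lower, and 0 remained called with camera's estimated correlation, where 1 had an unadjusted p under 0.05, while fry called 0 after adjustment and 11 before. Leaving out 1 library gave 684 genes higher and 391 lower without the first wild-type library, 684 and 390 without the second, 429 and 249 without the first KO library, 139 and 64 without the second, 1849 and 1596 without the first rescue library, and 498 and 274 without the second. Without the second KO library 42 of 73 named genes lost their call, Slc2a1, Lif, Ccl2, B2m and Tnfaip3 among them, and the members that rose numbered 4 for hypoxia, 7 for matrix, 5 for RAS-MAPK, 6 for interferon-stimulated and 1 for MHC class I genes; the median log2 fold changes of these lists were then 0.59, 0.54, 0.44, 0.49 and 0.30, against 0.63, 0.60, 0.53, 0.62 and 0.28 with all libraries, and all 5 still passed; without the second rescue library the medians were 0.40 for hypoxia and 0.25 for matrix genes, while the replication list passed at -0.18 and -0.33 without the first and the second KO library with 0 of its genes called, against 21 called lower without the first rescue library, 2 without the second and 14 with no filter, and the MHC class I list did not pass without the first rescue library (adjusted p = 0.095).

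Against wild type, the rescue kept many of the KO differences. In the rescue 1263 genes were higher and 1481 lower than in wild type, with 255 and 471 of them by at least 2-fold. Cxcl12 again had 0 counts, at least 133.1-fold lower, and Prom1, Mal and Celsr1 stayed below 1 CPM. Cxcl5, a chemokine, fell from 24.1 ± 1.09 CPM in wild type to 0.32 ± 0.45 in the rescue (adjusted p = 9.9e-07). Interferon-stimulated genes were higher in 34 of 37, also when adjusted over the list alone, with a median log2 fold change of 2.07 (camera adjusted p = 7.1e-27, and adjusted p = 0.185 with an estimated correlation). Iigp1 was among the 5 genes with the highest fold changes. MHC class I genes were higher in 19 of 20 and NF-kB targets lower in 25 of 29, or 19 and 26 adjusted over the list alone, and these were the 2 lists of 17 that also passed with an estimated correlation, both at adjusted p = 0.045. Hypoxia genes were lower in 12 of 34, also when adjusted over the list alone (adjusted p = 5.5e-04, and adjusted p = 0.573 with an estimated correlation). Without the first wild-type library 417 genes were called higher and 691 lower in the rescue, and without the second 552 and 776. The hypoxia list did not pass without the first rescue library (adjusted p = 0.185), and its lower members numbered 3 and 7 without the first and the second wild-type library and 21 without the second rescue library.

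Of the genes changed in the KO, 1422 moved back in the rescue and 2409 were still changed against wild type, and a gene could be in both counts. Genes higher in the KO moved back in 563 of 2867 and genes lower in the KO in 859 of 2905, where independent lists would share 168.7 and 242.5. Hypoxia and glycolysis genes moved back in 28 of 31, or 90.3%, against 24.3% of the other changed genes (Fisher's exact test, adjusted p = 3.5e-13). Collagens and matrix proteins moved back in 15 of 24 (exact adjusted p = 0.001). RAS-MAPK output genes did in 14 of 24 (exact adjusted p = 0.003). Among interferon-stimulated genes 1 of 34 did (exact adjusted p = 0.007), namely Isg20, which had fallen in the KO. The exact test was outside the plan and treats genes as independent. Members of these lists were correlated, with estimates of 0.726 for hypoxia, 0.577 for matrix, 0.375 for RAS-MAPK and 0.330 for interferon-stimulated genes. In the rescue against the KO each of the 4 lists had adjusted p = 0.542 in camera with an estimated correlation. WNT targets, with an estimate of -0.025, had the same value, so it does not measure the correlation. NF-kB targets moved back in 6 of 27 (22.2%, against 24.6% of the other changed genes), with 6 further from wild type and a median ratio of 0.91. Cytokines and chemokines moved back in 4 of 23 (17.4%, against 24.7%), with 3 further and a median ratio of 0.94. The genes that moved back with the largest fold changes by the rule included Has2 and Lamb3 among those lower in the KO, with Pgf, whose rescue call was lost without either KO library, and Atoh8, Cpm, Wnk4, Myo15b and Serpinb1a among those higher. Kcnmb1, Col3a1, Gpnmb, Cxcl12, Lbp and Celsr1 were among the genes still changed. The median rescue change was 0.55 of the KO change, with 0.70 in the first rescue library and 0.42 in the second.

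The comparisons share libraries, which alone gives some overlap. With no effect simulated, on average 0.2 genes moved back and 0.2 were still changed. Such overlaps were bound to be near 0, since on average 1.55 genes were then called in the KO against wild type. With the KO effect but no return, on average 0.3 moved back and 5200.4 were still changed, against 1422 and 2409 observed. The median ratio in the simulations without return was 0.968 (range 0.962 to 0.975 over 20 simulations). All simulated libraries had the same spread for a gene, and genes were drawn independently. These simulated values therefore do not cover the larger spread between the rescue libraries (biological coefficient of variation 10.5%, against 5.1% in wild type and 6.1% in the KO). Across genes, which are not independent replicates, the KO change and the rescue change against the KO had a correlation of -0.518, against -0.469 simulated with no effect and -0.102 with the KO effect but no return, and a covariance of -0.212 against -0.020 and -0.025. For the changes of KO and rescue against wild type the correlation was 0.856 against 0.491 and 0.961, and the covariance 0.581 against 0.022 and 0.833, in the same order. With 2 libraries per group no split of the controls left 2 libraries in each part, and part of the excess over independent lists may come from the shared controls. The count of genes moved back was 785 and 843 without the first and the second wild-type library, 529 and 171 without the first and the second KO library, and 2817 and 616 without the first and the second rescue library. The count still changed was 960 and 1213 without the wild-type libraries. Without the second KO library 4 hypoxia genes were called higher in the rescue than in the KO, with the list median at 0.59 against 0.63, and without the second rescue library the median was 0.40.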

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

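The tests without Gm42418 and mitochondrial genes (2861 genes higher and 2906 lower in the KO), and of each gene list without each library, were chosen only after the result was seen. Counts of called genes over all genes tested, with RLE size factors, a stricter filter, no filter and limma-voom, stayed within 1.5 times of the reported ones. No scaling moved the median of all genes by over 0.1. Counts within single lists could move further. With no filter 14 replication genes and 9 cholesterol genes were lower in the rescue than in the KO, against 8 and 2 reported. DESeq2 gave 353 genes lower in the rescue than in the KO, 693 higher in the rescue than in wild type, 877 moved back and 1511 still changed. With only the 2 groups compared, 667 genes were higher and 377 lower in the rescue than in the KO and 892 moved back. A test against a 1.5-fold change gave 479 and 927 genes for the KO, 24 and 14 for the rescue against the KO, 198 and 353 for the rescue against wild type, 32 moved back and 455 still changed, by its stricter null. The replicate numbers did not pair the libraries (correlations of within-group differences 0.00, -0.25 and -0.23). A replicate block gave 429 genes lower in the rescue than in the KO and kept the other counts of called genes over all genes tested within 1.5 times. The log2 fold change of Irak4 passed the threshold at -0.84 with no filter, -0.85 with only 2 groups and -0.87 with the replicate block. It ranged from -0.89 to -0.80 with a library left out. The fit of only wild type and KO leaves out the spread of Irak4 between the rescue libraries (492.2 and 211.2 CPM). Its quasi-likelihood test gave adjusted p = 4.2e-07. The fits with no filter and with the replicate block included the rescue libraries, so that spread was not shown to be the only reason. Has2 ranged from -3.07 to -2.28. With a library left out, the lone sample being assumed to vary like the other groups, genes higher in the KO ranged from 1688 to 3297 and lower from 2005 to 3414, higher in the rescue than in the KO from 139 to 1849 and lower from 64 to 1596, higher in the rescue than in wild type from 417 to 1699 and lower from 691 to 1953, moved back from 171 to 2817 and still changed from 960 to 3395, and the median ratio from 0.41 to 0.69. Lists called numbered 18 to 19, 12 to 14 and 16 to 19 for the 3 comparisons. An estimated correlation in camera left 0, 0 and 2 lists, and for the rescue against the KO, where 1 list had an unadjusted p under 0.05, fry called 0 in a direction (11 unadjusted) and 20 in either. Of 170 genes and comparisons chosen by the naming rule, without Irak4 and Has2 in the KO against wild type, 127 kept their call in every alternative that tested them, 43 lost it in at least 1 and 0 changed direction; the tests against a 1.5-fold change and without Gm42418 were not part of this count, and for the KO against wild type Cela1 was the 1 that lost it. Groups of 2 allow no test for an outlying library, and at 7605328 to 11505983 counts a gene at 0 is shown only to lie below its floor.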

Other observations

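The tests of mixing at the needed share, of the amount of Irak4 mRNA, of chromosome 15 with separate wild-type libraries, and of both explanations for the interferon-stimulated genes were chosen only after the result was seen.

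Other lists also moved in the KO. Matrix proteases and their inhibitors fell in 15 of 23 and rose in 1, also when adjusted over the list alone (camera adjusted p = 1.7e-04, and adjusted p = 0.309 with an estimated correlation). Plaur and Plat were among them. YAP and TAZ targets fell in 18 of 25 and rose in 1, also when adjusted over the list alone (adjusted p = 8.3e-06, and adjusted p = 0.268 with an estimated correlation). F3, the tissue factor gene, fell from 592 ± 24.8 to 122.7 ± 19.3 CPM. In the rescue 9 of the 25 rose over the KO, or 14 adjusted over the list alone, Ankrd1 and Igfbp3 among them (adjusted p = 8.0e-06, and adjusted p = 0.542 with an estimated correlation). TGF-beta targets fell in 19 of 27 and rose in 3, or 20 and 3 adjusted over the list alone (adjusted p = 1.9e-04, and adjusted p = 0.268 with an estimated correlation). Id3 rose from 23.2 ± 0.22 to 95.5 ± 12.4 CPM. WNT targets fell in 9 of 14 and rose in 1, also when adjusted over the list alone (adjusted p = 9.0e-04, and adjusted p = 0.217 with an estimated correlation). Epithelial markers fell in 12 of 19 and rose in 1, also when adjusted over the list alone (adjusted p = 1.7e-04, and adjusted p = 0.268 with an estimated correlation). Mesenchymal markers fell in 11 of 20 and rose in 2, or 12 and 3 adjusted over the list alone (adjusted p = 0.005, and adjusted p = 0.309 with an estimated correlation). Cdh1, the E-cadherin gene, went from 378 ± 21.9 CPM in wild type to 204.8 ± 40.2 in the KO and 119 ± 30.4 in the rescue, and its call in the rescue against the KO was lost without the second KO library. Cdh1 was chosen after its KO values were seen, outside the naming rule for that comparison.

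The unfolded protein and amino acid stress list had 18 of 36 lower and 9 higher in the KO, or 19 and 9 adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.613 with an estimated correlation). It did not pass without the second wild-type library (adjusted p = 0.084) or the second KO library (adjusted p = 0.109), or with a stricter filter (adjusted p = 0.051). The p53 targets (adjusted p = 0.193), cholesterol genes (adjusted p = 0.272) and NRF2 targets (adjusted p = 0.792) did not pass in the KO against wild type. In the rescue against the KO, NRF2 targets fell in 7 of 24 and rose in 2, also when adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.542 with an estimated correlation), with 2 and 0 called without the second KO library and 10 and 3 without the first rescue library. Cholesterol genes fell in 2 of 25, or 7 adjusted over the list alone (adjusted p = 6.6e-04, and adjusted p = 0.570 with an estimated correlation), with 0 called without either KO library, 15 without the first rescue library and 9 with no filter. In the rescue against wild type they fell in 11, or 14 adjusted over the list alone (adjusted p = 3.4e-05, and adjusted p = 0.470 with an estimated correlation), and in 5 to 17 with a library left out. Gclc fell from 168 ± 38.2 to 77.7 ± 18.2 CPM and the iron-storage gene Fth1 from 1029 ± 63.8 to 684 ± 55.8, in the rescue against the KO, a call lost for Fth1 without the second KO library. Markers of other cell types were mostly not tested for low counts: 21 of 22 immune, 10 of 18 fibroblast, 9 of 14 endothelial and 21 of 24 pancreas markers. The fibroblast (adjusted p = 0.798) and endothelial (adjusted p = 0.534) lists did not pass, although Cdh5, a cadherin of endothelial cells, rose from 3.29 ± 0.46 to 23.2 ± 10.3 CPM. Pdx1, a pancreatic transcription factor, rose from 54.3 ± 4.44 to 117.4 ± 14.7 CPM in the KO.

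The rescue libraries lay between the KO and wild type. Chance return was argued against, since genes chosen on the first wild-type and KO libraries had a median ratio of 0.59 on the second ones, where at least 0.9 was predicted. For mixing with wild-type cells or RNA, the planned test came out in its favour: over 25 genes nearly off in the KO, the interquartile range of the wild-type fraction was 0.043 and 0.130 in the 2 rescue libraries, under the 0.2 set for a mixture. That range was narrow because the fractions lay near 0, with medians of 0.011 and 0.045, against 0.274 and 0.573 over 2083 other genes that fell, so a mixture at the share needed for the return was argued against by a later test, while a small one stays open. Whether the amount of Irak4 mRNA sets the return cannot be told apart from other differences between 2 single libraries: the one with more Irak4 (492 against 211 CPM) had a ratio higher by 0.28, so it lay nearer the KO, and an effect of Irak4 itself was not tested.

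Interferon-stimulated genes were higher in the KO and higher again in the rescue, and 19 of the 34 changed in the KO moved further. Immune cells in the cultures are argued against by the highest median of 0.13 CPM in any KO or rescue library over Ptprc, Lyz2, Cd74, Tyrobp, Fcer1g, Laptm5 and Coro1a. Infection with viral vectors, or selection of the infected cells, cannot be told apart from the loss of Irak4, since the labels name no group infected without it; the median log2 fold change of the list was 0.62 in the rescue against the KO. A return in the rescue, as loss of Irak4 alone would predict, was seen for 1 of the 34 genes, Isg20, which had fallen in the KO. It was seen for 0 of the 33 that had risen, and the median ratio of the 34 was 1.36. Loss of Irak4 is still not excluded, since any effect of the undescribed rescue construct was not measured apart. A difference between the cell populations also stays open.

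Some chromosomes were shifted as a whole in the KO. Over 455 genes of chromosome 15 the median log2 fold change was -0.20 against all genes, below each of 10000 random lists matched on expression (lowest -0.13), and all 11 of its 10 Mb bins were lower. Chromosomes 3 (-0.15) and 1 (-0.09) also lay below all their random lists, and chromosomes 8 (0.12) and 11 (0.08) above all of theirs. The random lists held scattered genes and do not cover neighbouring genes that move together, so they do not single out chromosome 15. GC content and gene length are argued against, since 1.04 of the shift was left after a trend on both was removed. Copy-number differences between the wild-type and the knockout-derived cells may account for it as a hypothesis: against separate wild-type libraries the shift was -0.19 in the KO and -0.22 in the rescue, and -0.20 and -0.21 with these exchanged, while the 2 libraries of a group differed by 0.00 in wild type, -0.07 in the KO and 0.07 in the rescue. No DNA was measured here, the rescue cells derive from the KO, and an effect of Irak4 loss was not excluded.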
